A study of Mus musculus with 86 samples.

How the data were processed

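The deposited values were taken as linear intensity, summarised by GCRMA per the submitters' processing notes, which give no version. Every array had a median of 1, so the authors' values were read as divided by each array's own median, and log2 of the value was used. No value was 0 or negative. The 75th percentile ran from 3.49 to 8.37 over the arrays that did not fail, and was 1.28 in treated B2KO replicate 10. The labels state that mice were assigned to treatment at random and that 10 µg of total RNA was used for labelled cRNA. They do not explain the name B2KO further. Adrb1 and Cpt1b were not analysed here.

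Probe sets were matched to genes by the platform's annotation, and symbols were updated by gene number from the RefSeq gene table of assembly GRCm38.p6. Of 45101 probe sets, 64 controls, 932 with several symbols and 9160 with none were set aside, and 34945 with 1 symbol gave 18193 genes. Of these probe sets 99.4% were found there by gene number. The probe set of the highest mean over all arrays stood for its gene. The plan named a filter of log2 4 on the highest group mean for values on the usual GCRMA scale. Because the values were scaled to a median of 1, the stated fallback applied, above the median of all values (log2 0), and 11962 genes remained. The stricter filter was placed 2 log2 units above it and kept 8728. Probes over a strain polymorphism can read low without a change of RNA, which matters for comparisons between lines and less for treated against untreated mice of 1 line.

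A duplicate was defined by r over 0.9999 between 2 arrays. Treated B2KO replicates 4 and 9 met it with r = 0.99999976, where the next pair had 0.982, and the 2 were averaged on the log2 scale and counted as 1 array, a step taken after the duplicate was seen, so that 85 arrays entered the fit. An array counted as failed at a median r under 0.7, as in doubt by RNA at a Gapdh difference over 2, and as in doubt by strain if the distance to its own background was at least 0.9 of the distance to the nearest other, over 200 marker probe sets. One array failed, 2 were in doubt by strain and 5 by RNA. They were kept in the values given and left out in alternatives without the failed array, without 3 arrays and without 8 arrays. Untreated B2KO replicate 1 was female by Xist (3.20, against −2.21 to 0.59) and Eif2s3y (−0.57, against 2.06 to 6.65), and the other 85 deposited arrays were male by these genes.

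Genes were compared with limma 3.58.1 in R 4.3.3, in 1 linear fit over the 8 groups with plain empirical Bayes moderation. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, with limma adjusted p under 0.05 as the threshold. The 14 comparisons were the isoproterenol effect in each of 4 lines, 6 differences between effects and 4 baselines between untreated lines. Lists of genes were written from general knowledge before the data were examined, and so were the groups, the comparisons, the rule for naming genes, the threshold and most of the alternative settings. Lists were tested by camera with a preset correlation of 0.01, adjusted over the lists of a comparison, again with the correlation estimated from the residuals, and by fry. Of all list tests, 78 passed with the preset correlation and 2 with the estimated one. The sample labels number replicates within groups, and this number was tried as a random block through duplicateCorrelation.

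Genes were named by rule: those fixed in advance, the 8 largest rises and falls past the threshold in each isoproterenol effect, the 8 largest each way in the derivation comparison and 4 each way in the other differences, 5 each way in the baselines, up to 4 members of each list described, and 6 each way among genes past the threshold in all 4 lines. Transcripts without a gene name were passed over.

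The derivation score used genes with an adjusted p under 0.05 in the derivation comparison and an unadjusted p under 0.05 with the same sign against C57BL/6 in both FVB and B2KO. For B6129SF2/J they were chosen in the arrays of the other lines. Each gene's value in an array was taken relative to the mean of the untreated arrays of its line, and the score was the mean over rising genes minus the mean over falling genes, halved. For the other lines each array was scored with genes and untreated means found without it. The difference in B6129SF2/J was tested by permutation of its treatment labels, with 1e+05 resamples.

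A self-test simulated arrays from the mean of each line plus normal noise with each gene's residual SD, in groups of the same sizes, and added known changes to 200 genes in the treated arrays of FVB, B2KO and B6129SF2/J. For the FVB effect 5.97% of changes of 0.5 log2 were found, 56.7% of changes of 1 and 100% of changes of 2, with 13 unchanged genes called among 11924. For the derivation comparison the shares were 1.49%, 32.8% and 100%, with 4 unchanged genes called.

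The alternative settings chosen before the data were examined were no filter, the stricter filter, the mean of all probe sets of a gene, leaving out probe sets with suffixes for shared sequence, quantile normalization, centring on the median of the genes, a fit on the groups compared only, trend and robust moderation, array weights, the first component of the residuals as a covariate, sex as a covariate, the replicate block, a fold of at least 1.5, and each array of the groups compared left out in turn. The component of the residuals leaves every change as it is. It lies mainly on treated B2KO replicate 10 (0.762, the next largest 0.211), so it takes up that array's spread but not its share in the B2KO mean. The alternatives without the failed array, without 3 arrays, without 3 arrays and with quantile normalization, without 8 arrays, and quantile normalization of the lists were added after the values had been seen. Tables were read with the R package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Raw image data were not used here.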

Results

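RNA of mouse hearts was read on 86 Affymetrix arrays of 45101 probe sets. The mice belonged to 4 lines: the inbred lines FVB and C57BL/6, the line that the labels call B2KO, and the hybrid line B6129SF2/J. In each line, some mice received a 14-day infusion of isoproterenol, an agonist of beta-adrenergic receptors, at 120 µg/g/day, and the others received no treatment. The treated and untreated arrays compared numbered 12 and 10 in FVB, 10 and 11 in C57BL/6, 10 and 10 in B2KO, and 12 and 10 in B6129SF2/J. An 11th treated B2KO array duplicated another, and the 2 were averaged and counted once. Per the study's description, infusion was followed by systolic dysfunction in FVB and B2KO and by diastolic dysfunction in C57BL/6, and 83 genes found in these lines were then applied to B6129SF2/J. Each gene was read from 1 probe set, and 11962 genes were compared. Changes are log2 differences between group means, given ± SE, treated minus untreated.

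The arrays differed in quality. Treated B2KO replicate 10 had a median correlation of 0.573 with the other arrays, against 0.831 to 0.963 for the remaining 85. Its Gapdh control probe set at the 3′ end read 3.31 on the log2 scale, against 8.69 to 11.2. Treated FVB replicate 2 lay nearer to the C57BL/6 background than to FVB at strain marker probe sets, with root mean square distances of 0.903 and 2.81. Treated B2KO replicate 7 lay as far from its own background as from another, at 1.56. In 5 further arrays the 3′ Gapdh signal exceeded the 5′ signal by more than 2 log2 units: untreated C57BL/6 replicate 11 (7.43), untreated B2KO replicate 8 (7.31), untreated B6129SF2/J replicate 8 (4.35), treated B6129SF2/J replicate 7 (2.25) and untreated FVB replicate 10 (2.06). All of these arrays stayed in the values given, unless stated otherwise. Their number and the spread between them limit the precision: the median SE of a change was 0.25 in FVB and B6129SF2/J and 0.26 in C57BL/6 and B2KO. The p-values measure the spread between arrays, which the labels describe as separate mice, although they speak of 20 mice for lines that have 21 or 22 arrays.

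**Figure D1:**
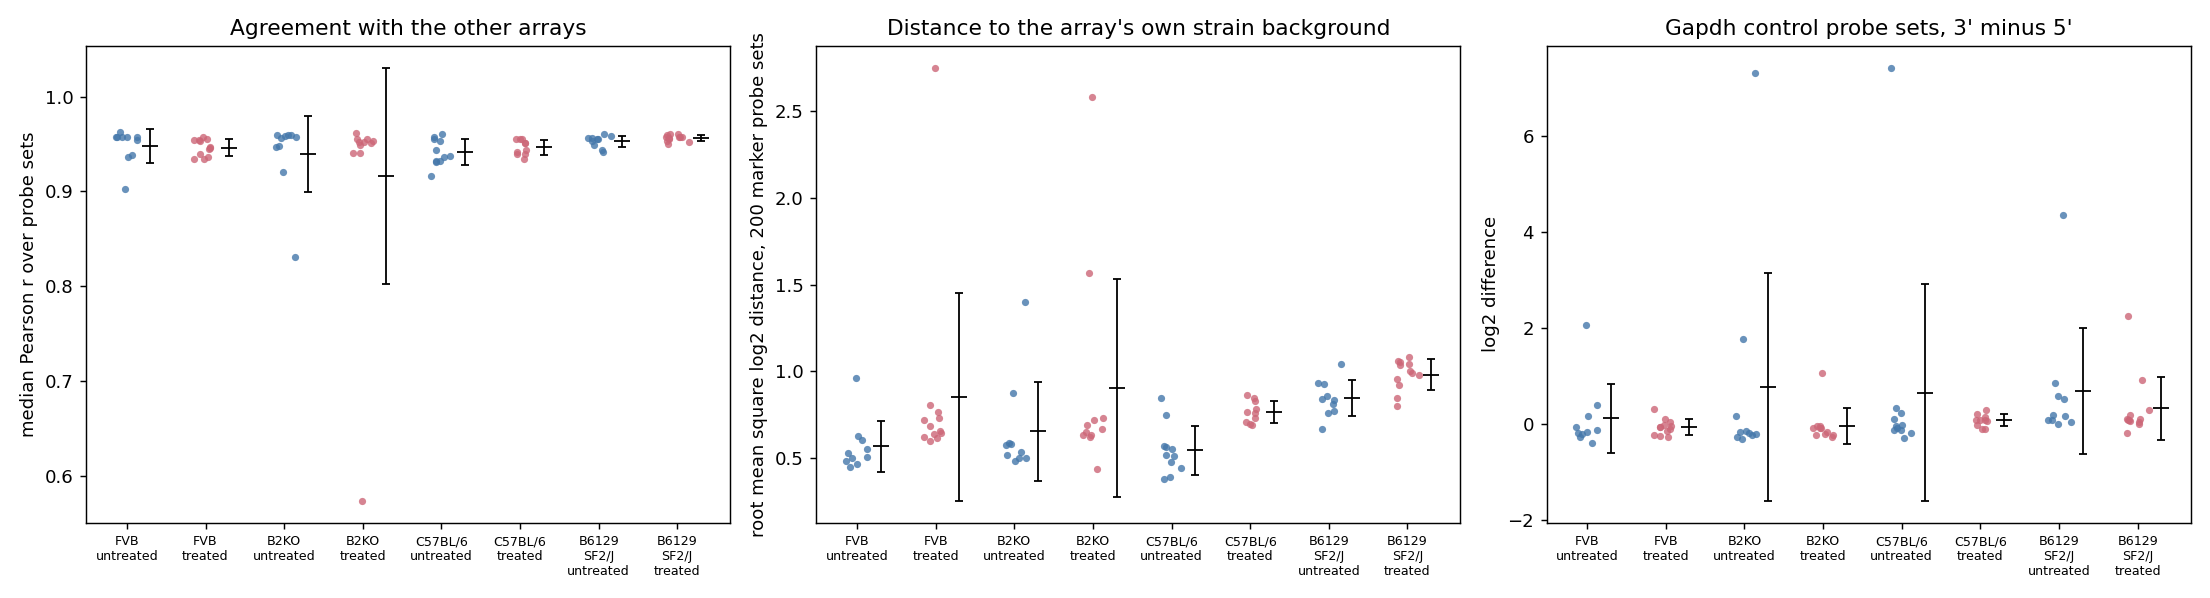
Median Pearson r of each array with the others, root mean square log2 distance to the array's own strain background over 200 marker probe sets, and log2 difference of the Gapdh control probe sets (3′ minus 5′), by line and treatment; points are arrays and bars are mean and SD. Treated B2KO replicate 10 lies at r = 0.573, treated FVB replicate 2 at a distance of 2.75 (from B2KO, the nearer of FVB and B2KO, which were taken as one background), and untreated C57BL/6 replicate 11 at a Gapdh difference of 7.43.

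The first question was which genes isoproterenol changed in FVB. Rad51b, which encodes a protein of homologous recombination, rose by 3.76 ± 0.52 (adjusted p = 5.45e-07, 11 of 12 treated arrays above the untreated mean). Its untreated mean of −1.35 lay under the array median, so the size of this rise rests on a dim baseline. Dio2, the deiodinase that activates thyroid hormone, rose by 2.54 ± 0.31 (adjusted p = 1.11e-08, 12 of 12). Postn (periostin, a matrix protein of activated fibroblasts) rose by 2.39 ± 0.34 in 11 of 12 arrays, the Wnt antagonist relative Sfrp2 by 2.38 ± 0.32 and the matrix gene Cilp by 2.37 ± 0.36 in 12 of 12 each. Top2a, Clec4n and Slc25a37 rose by 2.17, 2.10 and 2.04, of which Top2a did not pass when its probe sets were averaged (0.64, adjusted p = 0.0613). Timp4 (−2.37 ± 0.42), the thioesterase Acot1 (−2.22 ± 0.27), Retnla (−2.12 ± 0.32), Gnb3 (−1.82), Penk (−1.77), Frem2 (−1.74) and Cngb3 (−1.72) fell in at least 11 of 12 treated arrays. Skeletal actin (Acta1) fell by 1.76 on the log2 scale (SE 0.50, adjusted p = 0.0479, 12 of 12), a call that ended without a filter on dim genes (adjusted p = 0.0632), with trend and robust moderation (0.0626) and with probe sets averaged (0.0513). Leaving out single FVB arrays ended it for 17 of 22, with adjusted p from 0.0217 to 0.0939.

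In FVB, 181 genes passed the threshold, 108 higher and 73 lower with treatment. With each array centred on the median of its genes, 501 passed, 148 higher and 353 lower. Leaving out treated FVB replicate 2 raised the count to 283. In that array Postn read 5.47, within the untreated range of 5.02 to 6.48, and Rad51b read −2.55.

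Genes of the extracellular matrix and fibrosis list rose together in FVB: 16 of 38 rose over all genes tested and 24 when adjusted over the list alone, none fell, and the median was 0.92 (adjusted p = 1.22e-33; adjusted p = 0.0229 with an estimated correlation). Mfap4 (1.78) and Tnc (1.83) stood beside Postn and Cilp. Cell cycle genes rose in 8 of 21 cases, 17 when adjusted over the list alone (median 1.00, adjusted p = 1.41e-22; adjusted p = 0.0192 with an estimated correlation), among them Top2a, Mki67 (1.87), Ccna2 (1.60) and Prc1 (1.48). Of 4 erythroid genes Alas2 (1.96) and Slc4a1 (1.46) rose, and all 4 did when adjusted over the list alone (median 1.29, adjusted p = 2.82e-05). That call was lost with an estimated correlation (adjusted p = 0.0768). Smaller shifts were higher for interferon response (median 0.39, adjusted p = 0.000107), beta-adrenergic signalling (0.28, 0.00438) and macrophage and monocyte genes (0.29, 0.00438), and lower for fatty acid oxidation (−0.28, 0.000661). Over all genes tested, Lgals3 among the macrophage genes was the 1 member of these 4 lists that passed. When adjusted over the list alone, 2 rose in each of the first 3 and 0 fell in the last. Each of the 4 lists lost its call with an estimated correlation (adjusted p = 0.504 for interferon response and adjusted p = 0.917 for the other 3).

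The same infusion was compared with no treatment in C57BL/6. Junb, a transcription factor of the early response, rose by 3.06 ± 0.43 in 10 of 10 treated arrays (adjusted p = 1.93e-07), and Timp1, an inhibitor of matrix proteases, by 3.01 ± 0.40 in 10 of 10 (6.26e-08). Hnrnpl rose by 3.10 ± 0.58 and Otub1 by 2.88 ± 0.48, each in 10 of 10. Fos (2.86 ± 0.62) was above the untreated mean in 7 of 10 and the uncoupling protein Ucp1 (3.05 ± 0.89, adjusted p = 0.00934) in 8 of 10. Clec4d (2.85) and Dct (2.84) completed the largest rises. Their sizes rest in part on dim baselines: untreated Clec4d reached at most −0.55, under the array median, and Timp1 averaged 0.52. Junb, Hnrnpl, Otub1, Fos, Ucp1 and Dct read under the array median in some untreated arrays. Sema6c fell by 3.53 (SE 0.55), B3galt2 by 2.84 (SE 0.31), Cngb3 by 2.76 and Lgi1 by 2.68, each in 10 of 10. Cryl1 (−2.73 ± 0.55) fell in 9 of 10, and Med18 (−2.31), Uroc1 (−2.30) and Frem2 (−2.22) in 10 of 10. Several of these genes also varied among the untreated C57BL/6 arrays: Sema6c ranged from −0.27 to 4.28, Cryl1 from 1.35 to 7.20 and Hnrnpl from −1.73 to 3.90. In 6 of the 16 genes named the SD there exceeded that in untreated FVB and B6129SF2/J, and in others it was smaller, as for Cngb3 (0.506 against 0.891 and 0.833) and Lgi1 (0.519 against 1.41 and 0.616).

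In C57BL/6, 2335 genes passed, 1500 higher and 835 lower. The split turned under quantile normalization (1293 higher, 1657 lower) and with arrays centred on their genes (1266 higher, 1957 lower). All 16 genes named for this line passed in their direction under both.

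Matrix genes rose in C57BL/6 as well: 27 of 38 over all genes tested, 31 when adjusted over the list alone, median 1.25 (adjusted p = 4.58e-15), led by Timp1, Tnc (2.36), Cilp (2.19) and Postn (1.94). Immediate early genes rose in 10 of 15 cases, 12 when adjusted over the list alone (median 1.07, adjusted p = 2.23e-06), with Btg2 (2.11) and Ier2 (2.00) beside Junb and Fos. These genes also respond within minutes to the handling of animals and tissue. Both calls were lost with an estimated correlation (adjusted p = 0.669 each). Cell cycle genes (8 of 21, 10 when adjusted over the list alone, median 0.63, adjusted p = 0.000604) included Top2a (2.14), Cdk1 (1.72) and Ccna2 (1.69). Endothelial genes (7 of 13 by either adjustment, 0.76, 0.0162) included Cldn5 (1.51), Eng (1.37) and Cdh5 (1.32). Beta-adrenergic signalling (8 of 25 by either adjustment, 0.40, 0.0163) included Adra1b (1.58), Arrb1 (1.498) and the phosphodiesterase Pde3a (1.40). Antioxidant defence (7 of 17, 8 when adjusted over the list alone, 0.53, 0.0163) included Gclm (1.40), Hmox1 (1.40) and Sod3 (1.38). For these 4 lists the calls were lost, at adjusted p = 0.95 with an estimated correlation.

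In B2KO the median change of all genes was −0.28, and changes relative to it are given where stated. Most of this shift came from 1 array: without treated replicate 10, the failed array, it was −0.081. The relative values therefore rest largely on that array. Timp1 rose by 1.90 ± 0.41 (adjusted p = 0.00909, 8 of 10 treated arrays; 2.18 relative to the median), tenascin C (Tnc) by 1.76 ± 0.37 (adjusted p = 0.00554, 9 of 10; 2.05 relative) and the chemokine Ccl8 by 1.65 ± 0.39 (9 of 10; 1.94 relative). Dct (1.69), Cilp (1.41), Lgals3 (1.37), Clec4n (1.27) and Lman1l (1.08) also rose. Retnla fell by 1.89 (SE 0.34, adjusted p = 0.00112, 10 of 10; −1.61 relative), the calcium channel gene Cacna1g by 1.79 (SE 0.35, 10 of 10; −1.51 relative), and hepcidin (Hamp) and Ces1d by 1.66 each (10 of 10). Meig1 (−2.11), Car3 (−2.01, adjusted p = 0.0415), Tmem82 (−1.90) and Dmpk (−1.84) fell as well. Treated replicates 5 and 7 read no higher than the highest untreated B2KO array at Timp1 (0.75 and 1.06), Postn (5.97 and 4.70), Tnc (−0.31 and −1.24) and Dio2 (0.35 and −0.96).

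In all, 215 genes passed in B2KO, 10 higher and 205 lower. The split changed with the scaling and without treated B2KO replicate 10, while lower calls stayed the majority in each case. Under quantile normalization 178 passed (59 higher, 119 lower), and 43 did without treated replicate 10 (13 higher, 30 lower). Without that array and the arrays in doubt by strain markers 93 passed (38 higher, 55 lower). Leaving out other single arrays moved the count as well: treated replicate 5 to 844 (35 higher), 6 to 747, 3 to 682 and 2 to 103, and untreated replicate 5 to 367, 2 to 127, 6 to 111 and 9 to 104. A fit of the B2KO arrays alone called 0 genes (limma; 927 at an unadjusted p under 0.05, against 598 by chance). Of the 16 genes named, 11 passed without treated replicate 10, where Dct (adjusted p = 0.114), Cilp (0.0843), Car3 (0.191), Tmem82 (0.0892) and Dmpk (−1.18, 0.0746) did not. In the fit of the B2KO arrays alone 0 passed, and without the 3 arrays 15 did, with Car3 the exception (−1.59, adjusted p = 0.224).

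Relative to the median of all genes, matrix genes in B2KO stood 0.53 higher (3 of 38 rose, 8 when adjusted over the list alone, adjusted p = 4.89e-15), macrophage and monocyte genes 0.48 (1 of 20 by either adjustment, 2e-06), interferon response genes 0.46 (0 of 16, 1.69e-05) and cytokines and chemokines 0.29 (Ccl8 alone of 19 by either adjustment, 0.0024). Fatty acid oxidation genes stood lower by −0.54: Cpt2 (−1.40), Acaa2 (−1.40), Eci1 (−1.23), Acot2 (−1.17) and 2 more of 25 fell, 13 when adjusted over the list alone (adjusted p = 1.66e-05). These calls were lost with an estimated correlation (adjusted p = 0.351 for the matrix, macrophage and interferon lists, adjusted p = 0.388 for cytokines and adjusted p = 0.609 for fatty acid oxidation). Erythroid genes (0.67 relative, 0 of 4, adjusted p = 0.00971) lost theirs as well (adjusted p = 0.388 with an estimated correlation). Cell cycle genes (0.38 relative, 0 of 21, adjusted p = 0.00123), oxidative phosphorylation (−0.40, 0 of 28, 1 when adjusted over the list alone, 0.0113) and the tricarboxylic acid cycle (−0.34, 0 of 14, 8 when adjusted over the list alone, 0.0113) also lost their calls with an estimated correlation (adjusted p = 0.684, 0.88 and 0.775). Without the 3 arrays and with quantile normalization these 3 lists did not pass (adjusted p = 0.333, 0.0805 and 0.113).

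B6129SF2/J was the line to which the genes found in the others were applied. Dct, a tautomerase of melanin synthesis, rose by 2.98 ± 0.43, Tnc by 2.79 ± 0.35 (adjusted p = 2.36e-08), Timp1 by 2.75 ± 0.40 (6.02e-07) and Cilp by 2.71 ± 0.36, each in 12 of 12 treated arrays. The nuclear receptor gene Nr4a3 (2.68), the C-type lectin gene Clec4n (2.55) and the inducible chaperone gene Hspa1a (2.54 ± 0.68, adjusted p = 0.0149) rose in 12 of 12, and Tmprss13 (2.62) in 11 of 12. Jchain, the joining chain of IgM and IgA, fell by 3.32 (SE 0.63, adjusted p = 0.000189, 12 of 12) and the IgM heavy chain gene Ighm by 2.46 (SE 0.50, 12 of 12). Scgb1a1 (−2.98), Nnat (−2.56), Pdzd3 (−2.18) and Gnb3 (−2.13) fell in 12 of 12, and Plet1os (−2.73) and Nxpe4 (−2.34) in 9 of 12. The untreated arrays varied at Scgb1a1, with an SD of 3.97.

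There, 543 genes passed, 292 higher and 251 lower (405 higher and 607 lower with arrays centred on their genes). Matrix genes rose in 19 of 38 cases, 25 when adjusted over the list alone (median 1.05, adjusted p = 4.35e-32; adjusted p = 0.0581 with an estimated correlation, so the call was lost). Cytokines and chemokines rose in 5 of 19 cases, 8 when adjusted over the list alone (0.52, 4.69e-05), among them Ccl8 (1.59), Ccl2 (1.47) and Il33 (0.99). Beta-adrenergic signalling rose in 5 of 25 by either adjustment (0.20, 0.000406), with the receptor kinase Grk5 (1.38), Crem (1.23) and Pde4b (1.18). Fatty acid oxidation genes fell in 4 of 25 cases, 8 when adjusted over the list alone (−0.54, 2.67e-06): Acot2 (−1.22), the acylcarnitine carrier Slc25a20 (−1.01), Eci1 (−0.996) and Hadh (−0.78). With an estimated correlation these calls were lost (adjusted p = 0.3 for cytokines and adjusted p = 0.552 for the other 2).

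Among cell-type lists in B6129SF2/J, macrophage and monocyte genes (median 0.42, 2 of 20 rose and 3 when adjusted over the list alone, adjusted p = 0.000109) and fibroblast genes (0.41, 2 of 10 by either adjustment, 0.0119) stood higher. Lgals3 (2.52), Ctss (1.07), Mfap5 (1.497) and Pi16 (1.45) were their members past the threshold. Lymphocyte genes stood lower (−0.31, 0.0296), with Ighm, Cd79a (−1.08) and Cd79b (−1.04) the 3 of 7 that fell by either adjustment, a call lost under quantile normalization (0.0566). Interferon response (0.39, 0 of 16, 3 when adjusted over the list alone, 0.00344), cell cycle (0.28, Ccna2 at 1.26 alone of 21 by either adjustment, 0.0231), ion channels and gap junctions (−0.38, Scn4b at −2.09 alone of 14 by either adjustment, 0.024) and oxidative phosphorylation (−0.27, 0 of 28, 0.0111) passed as lists. Under quantile normalization oxidative phosphorylation lost its call (0.157). All 7 lists lost theirs with an estimated correlation: adjusted p = 0.552 for macrophages and lymphocytes, 0.557 for fibroblasts, interferon response and ion channels, and 0.755 for cell cycle and oxidative phosphorylation.

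**Figure D2:**
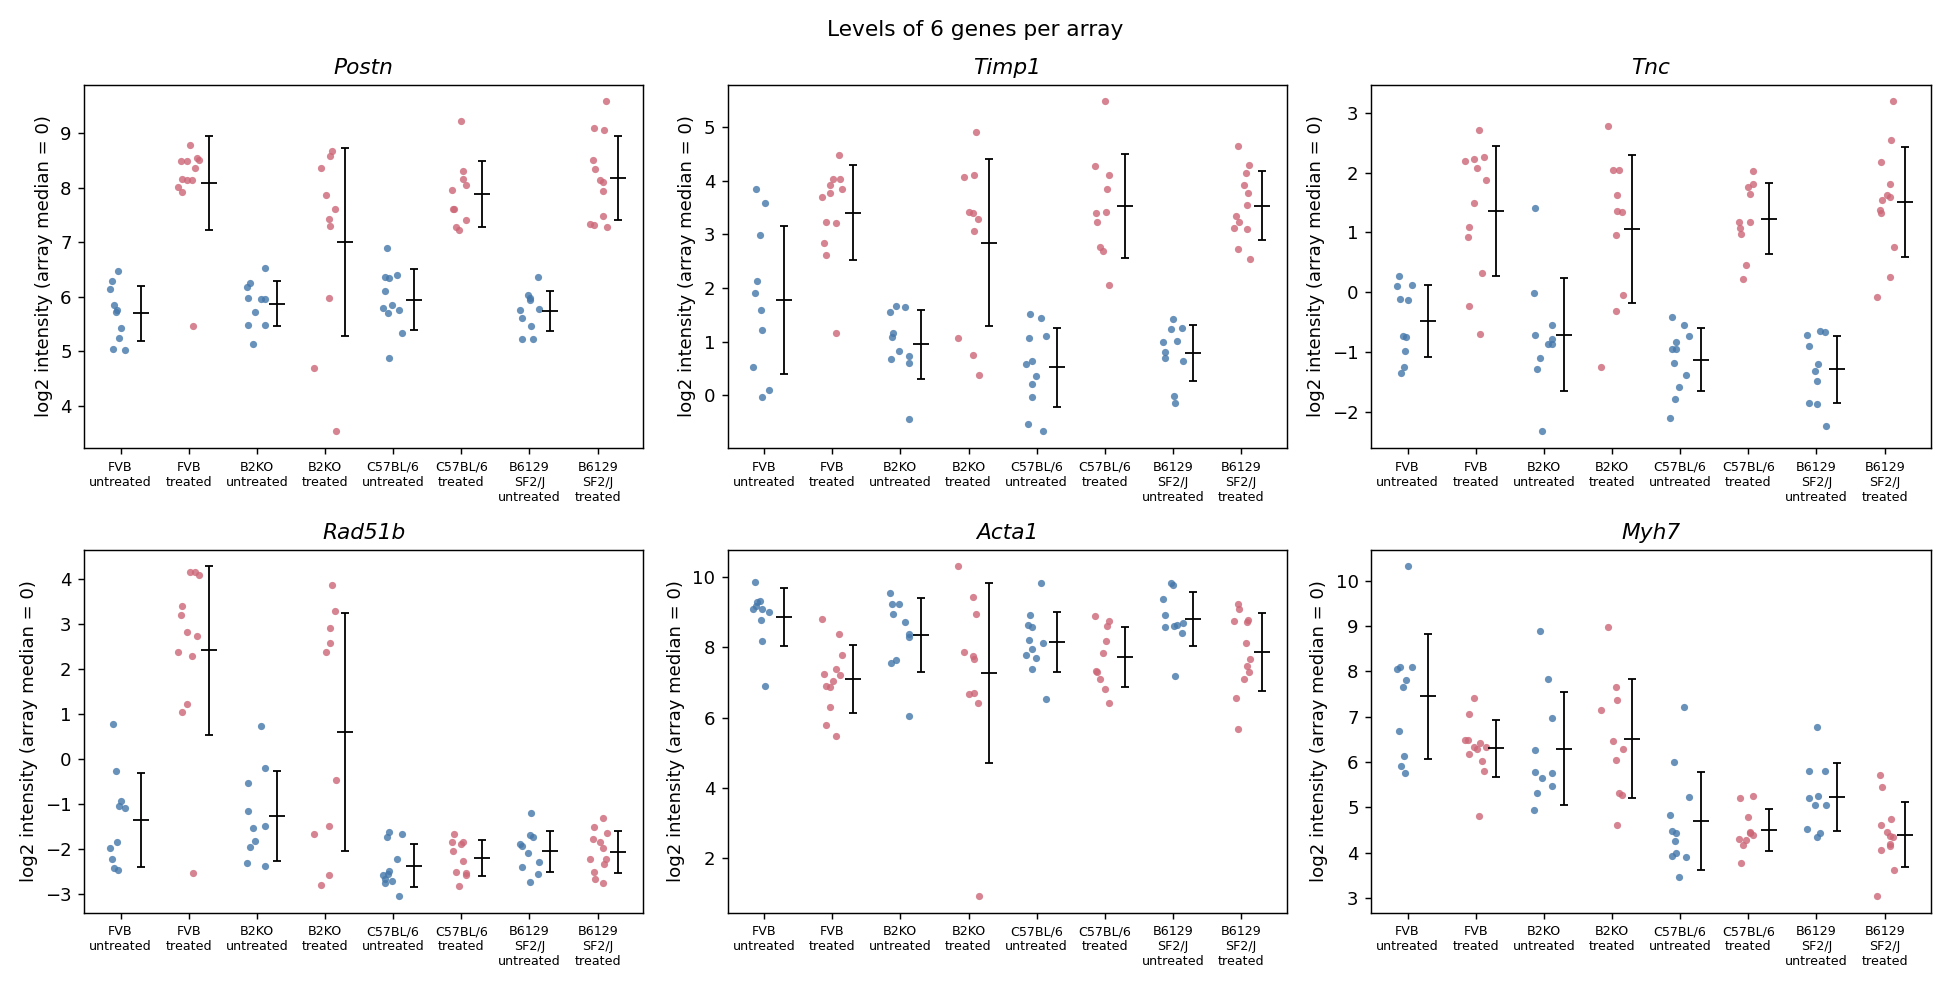
Log2 intensity (array median = 0) of Postn, Timp1, Tnc, Rad51b, Acta1 and Myh7 in untreated (blue) and treated (red) arrays of the 4 lines; points are arrays and bars are mean and SD. Postn rose from means of 5.70, 5.95 and 5.74 to 8.09, 7.89 and 8.18 in FVB, C57BL/6 and B6129SF2/J, and Rad51b had means of −2.21 and −2.07 in treated C57BL/6 and B6129SF2/J arrays against 2.41 in FVB.

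The next question was what the lines shared. In all 4 lines 6 genes rose: Timp1 (1.62, 3.01, 1.90 and 2.75 in FVB, C57BL/6, B2KO and B6129SF2/J), Tnc (1.83, 2.36, 1.76 and 2.79), Cilp (2.37, 2.19, 1.41 and 2.71), Clec4n (2.10, 1.39, 1.27 and 2.55), Lgals3, which encodes galectin-3 (1.55, 2.04, 1.37 and 2.52), and Dct (1.64, 2.84, 1.69 and 2.98). Tnc lay under the array median in every untreated C57BL/6 and B6129SF2/J array (at most −0.42 and −0.65), so the size of its rise rests on a dim baseline there. Another 9 genes fell in all 4 lines, with Acot1 (−2.22, −1.30, −1.51 and −1.49), Hamp (−1.69, −2.03, −1.66 and −0.95) and Frem2 (−1.74, −2.22, −1.24 and −1.45) among them. Angpt1, Asb5, Fbp2, Kcna1 and Snai3 were further named members. The B2KO calls were the weakest part of this overlap: the fit of the B2KO arrays alone called 0 genes, and over these genes other than Kcna1 and Snai3 adjusted p ran from 0.348 for Acot1, Hamp and Fbp2 to 0.612 for Lgals3 and Clec4n, and Timp1 and Tnc at 0.38. Without treated replicate 10 Dct (0.114), Cilp (0.0843), Asb5 (0.128) and Frem2 (0.0813) did not pass in B2KO. Neither did Asb5 under quantile normalization (0.121), Clec4n without probe sets of shared sequence (0.0629) or Angpt1 with probe sets averaged (0.0734). In other lines Angpt1 with probe sets averaged (0.343) and Hamp without a filter (0.0534) were lost in B6129SF2/J, and Fbp2 in the fit of the FVB arrays alone (0.0534). In 3 or more lines 37 genes rose and 36 fell. FVB and B6129SF2/J, which share no arrays, had 49 genes higher in both where independence gives 2.64, 38 lower in both where it gives 1.53, and 0 opposite. C57BL/6 and B6129SF2/J had 117 higher in both (36.6), 70 lower in both (17.5) and 22 opposite. Calls in all lines use 1 estimate of spread per gene from the shared fit, so they are not independent, and more overlap than these expected numbers can arise by chance. Across the 11962 genes, which are not independent replicates, the effects correlated with r = 0.54 between FVB and B6129SF2/J, 0.45 between B2KO and B6129SF2/J, 0.44 between FVB and B2KO, 0.40 between FVB and C57BL/6, 0.26 between C57BL/6 and B6129SF2/J and 0.16 between C57BL/6 and B2KO.

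Genes of cardiac stress and of the matrix were also chosen in advance. Acta1 passed in FVB (−1.76, adjusted p = 0.0479; lost in the 3 settings named above and without any 1 of 17 of the 22 FVB arrays) and not in C57BL/6 (−0.42), B2KO (−1.09) or B6129SF2/J (−0.93). Postn rose by 2.39, 1.94 and 2.44 in FVB, C57BL/6 and B6129SF2/J, and its rise of 1.13 ± 0.36 in B2KO did not pass (adjusted p = 0.0679). It passed without treated replicate 10 (1.52, 0.00879), 5 (0.0297) or 7 (0.0179), and with all arrays under quantile normalization (0.00125), centring (0.0149), array weights (0.00012) and a residual component (0.00201). The residual component left the change at 1.13 and took up mainly the spread of treated replicate 10. Collagen III (Col3a1) rose in FVB (1.06), C57BL/6 (1.03) and B6129SF2/J (1.08) and did not pass in B2KO (0.63, adjusted p = 0.103). Col1a1 rose in C57BL/6 (1.496, adjusted p = 0.0101) and did not pass in FVB (1.40, 0.0809), B2KO (0.14) or B6129SF2/J (1.06, 0.162). The natriuretic peptide genes Nppa (0.23, 0.70, −0.31 and 0.23 in FVB, C57BL/6, B2KO and B6129SF2/J) and Nppb (0.28, 0.32, −0.44 and −0.39) passed in no line with all arrays as deposited. Neither did the myosin genes Myh7 (−1.15, −0.20, 0.23 and −0.83) and Myh6 (0.26, 0.37, 0.05 and 0.10), nor Pln, Ankrd1, Pdk4 or Ppargc1a. Several of these outcomes changed with the setting. Without treated B2KO replicate 10 Nppa (adjusted p = 0.00133, against 0.13 with it) and Pdk4 (0.84, 0.031 against 0.0555) passed in C57BL/6, Ppargc1a (−0.996, 0.0279 against 0.139) and Col1a1 (0.0322) in B6129SF2/J and Col1a1 (0.0063) in FVB. With that array kept, Col1a1 in FVB passed without treated FVB replicate 2 (1.69, 0.00871) or untreated 6 (0.0473), under quantile normalization (0.0142) and with probe sets averaged (0.0442), and Pdk4 in C57BL/6 under quantile normalization (0.0407) and in the fit of its groups (0.0181). Nppa in C57BL/6 and Ppargc1a in B6129SF2/J also passed in fits of the groups compared (0.00845 and 0.00121), and Myh7 in B6129SF2/J did so there (0.0392) and with array weights (0.0453). Pdk4 in B2KO (−1.13, 0.0509) passed with the stricter filter (0.0393), and Acta1 with array weights in B2KO (0.0148) and B6129SF2/J (0.0107). Array weights also passed Myh6 (0.0234) and Pln (0.0282) in C57BL/6, and Col3a1 in B2KO passed under quantile normalization (0.0102). The calcium pump gene Atp2a2 rose in C57BL/6 (0.62, adjusted p = 0.0176), a direction that turned when all its probe sets were averaged (−0.07, 0.841).

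**Figure D3:**
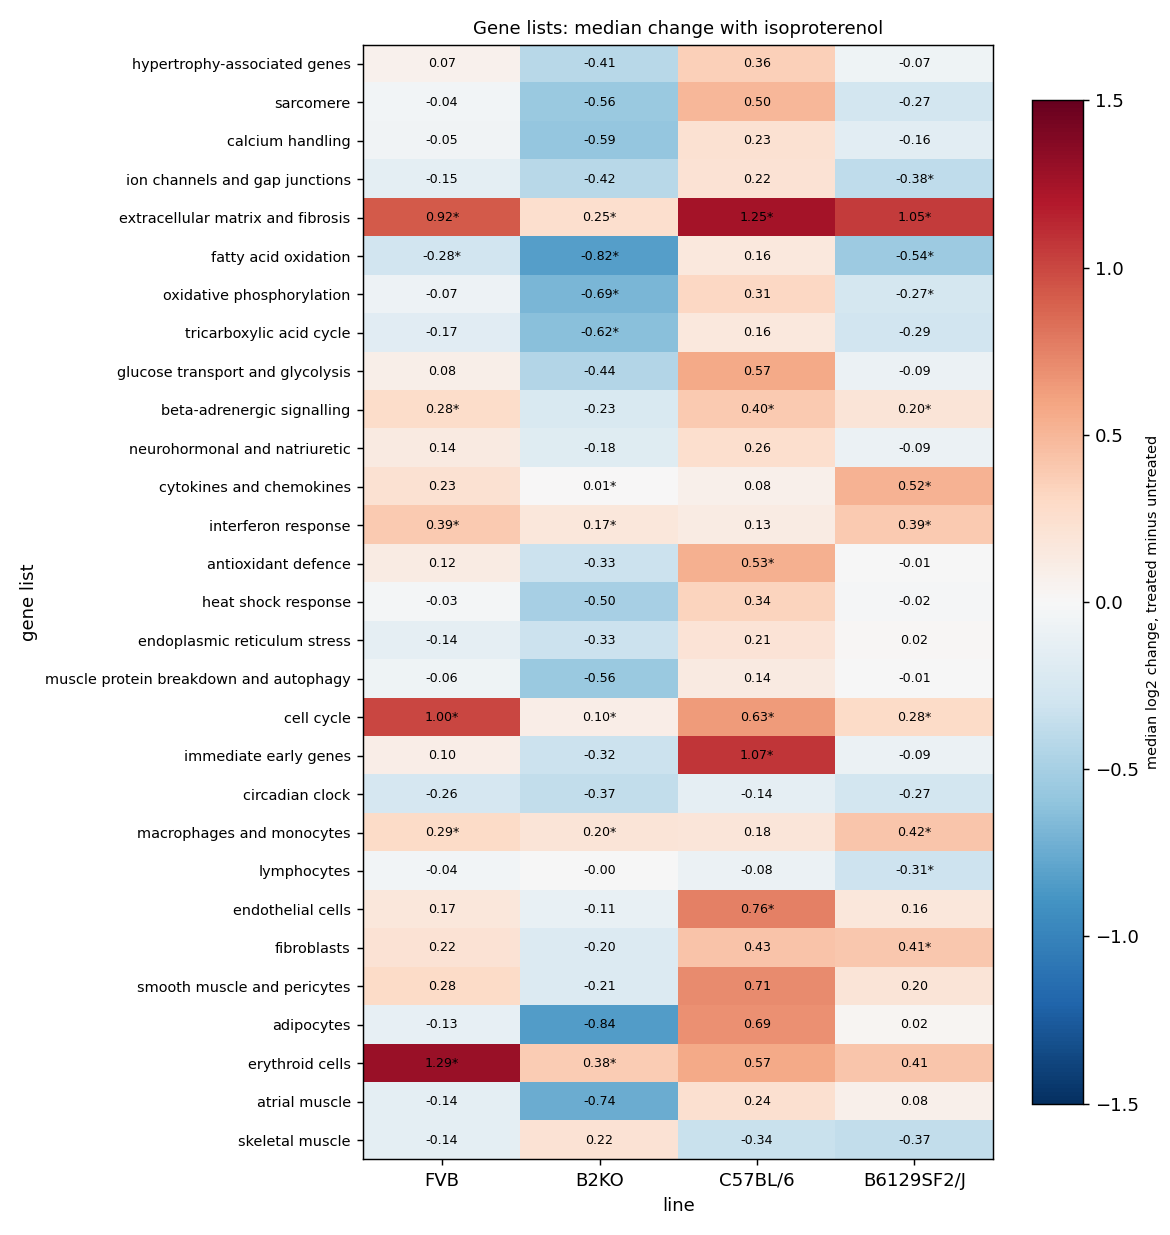
Median log2 change with isoproterenol of the genes in each of 29 lists, treated minus untreated, in FVB, B2KO, C57BL/6 and B6129SF2/J; colour and number give the median, and an asterisk marks an adjusted p under 0.05 in camera with a preset correlation. Extracellular matrix and fibrosis carries an asterisk in each line, with medians of 0.92, 0.25, 1.25 and 1.05, and B2KO medians include the −0.28 shift of all genes.

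The remaining lists passed in none of the 4 lines with all arrays as deposited. Adjusted p-values in FVB, C57BL/6, B2KO and B6129SF2/J were 0.869, 0.285, 0.727 and 0.824 for hypertrophy-associated genes, 0.723, 0.2, 0.0813 and 0.0603 for the sarcomere, 0.723, 0.77, 0.292 and 0.186 for calcium handling, and 0.456, 0.132, 0.721 and 0.855 for glucose transport and glycolysis. They were 0.145, 0.77, 0.603 and 0.855 for neurohormonal and natriuretic genes, 0.877, 0.77, 0.422 and 0.255 for the heat shock response, 0.456, 0.77, 0.986 and 0.855 for endoplasmic reticulum stress, and 0.275, 0.867, 0.168 and 0.824 for muscle protein breakdown and autophagy. For the circadian clock they were 0.315, 0.867, 0.721 and 0.341, for smooth muscle and pericytes 0.234, 0.104, 0.392 and 0.186, for adipocytes 0.805, 0.311, 0.0859 and 0.824, for atrial muscle 0.869, 0.77, 0.239 and 0.341, and for skeletal muscle 0.578, 0.305, 0.0813 and 0.56. Some passed under alternatives. Without treated B2KO replicate 10 the sarcomere was higher in C57BL/6 (adjusted p = 0.0123) and lower in B6129SF2/J (0.00637), glycolysis higher in C57BL/6 (0.00672), smooth muscle and pericytes higher in C57BL/6 (0.0437) and B2KO (0.0444), and adipocytes lower in B2KO (0.0376). Under quantile normalization the sarcomere was lower in B2KO (0.0232), and without 3 arrays and with quantile normalization glycolysis was higher in FVB (0.0348) and B2KO (0.0149) and smooth muscle and pericytes in B6129SF2/J (0.0455). Single members did pass: Hspa1a and Hspa1b (2.53) rose in B6129SF2/J, Pdia4 (1.86) and Slc8a1 (1.76) in C57BL/6, and the clock genes Dbp (−1.91), Nr1d1 (−1.31) and Hlf (−1.29) fell while Cry1 (1.26) rose in B6129SF2/J. Median, mean and test differed in sign in places: hypertrophy-associated genes in FVB had a median of 0.07 and a mean of −0.10 with the test pointing down. Atrial genes in FVB had −0.14 and 0.16 with the test up, and heat shock genes in B6129SF2/J −0.02 and 0.37 with the test up.

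The derivation question was which genes responded otherwise in the lines of systolic dysfunction (the mean of the FVB and B2KO effects) than in C57BL/6. The semaphorin gene Sema6c differed by 3.78 ± 0.68 (adjusted p = 0.000321), Rad51b by 2.65 ± 0.65 (0.00612), Cryl1 by 2.61 ± 0.67 (0.00884), Epcam by 2.37 ± 0.50, Uroc1 by 2.37 ± 0.53, Aif1l by 2.31, B3galt2 by 2.13 and Med18 by 2.11. Hnrnpl (−3.43 ± 0.71), Otub1 (−2.97 ± 0.58), the Ras-like gene Rasl10a (−2.80 ± 0.44), Junb (−2.78 ± 0.53, adjusted p = 0.000502), Fos (−2.64 ± 0.76, 0.0196), the glypican gene Gpc3 (−2.63) and Zbtb12 (−2.62) responded less or in the other direction. Ucp1 (−3.29 ± 1.09, 0.0416) did not pass under quantile normalization (adjusted p = 0.0799), without a filter (0.0516), with centring (0.0569) or in the fit of the groups compared (0.0643). It was also lost with trend and robust moderation (0.0581) and without 3 arrays (0.0576). Fos did not pass with array weights (0.0919), nor Cryl1 when its probe sets were averaged (0.45, 0.155). Most of these differences arose from the C57BL/6 change: Sema6c, Cryl1, Hnrnpl and Junb were among the largest changes there. Rad51b was the exception, rising in FVB from −1.35 to 2.41, with a B2KO mean of 0.60 and an SD of 2.64 among treated arrays, and lying at −2.37 and −2.21 in untreated and treated C57BL/6.

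The derivation comparison gave 1059 genes, 241 with a higher and 818 with a lower response in the systolic lines, with a median of −0.26 over all genes. Under quantile normalization, 1220 passed, 672 higher and 548 lower, and with arrays centred on their genes 498 were higher and 699 lower. Without untreated B2KO replicate 8 the count was 1848, and without untreated C57BL/6 replicate 1, 2 or 6 it was 666, 700 or 658. Immediate early genes had the lower response, 9 of 15 passing and 11 when adjusted over the list alone (median −1.18, −0.92 relative to all genes, adjusted p = 6.68e-06), with Btg2 (−2.55) and Ier2 (−2.11) beside Junb and Fos. That call was lost with an estimated correlation (adjusted p = 0.714). Fatty acid oxidation (−0.73, Pdk4 at −1.505 and Acads at −1.40 of 25 passing by either adjustment, 0.00768) lost its call too (adjusted p = 0.742 with an estimated correlation). Sarcomere (−0.76, Ldb3 at −0.96 and Tnni3 at −0.83 of 16, 4 when adjusted over the list alone, 0.0419), oxidative phosphorylation (−0.57, 0 of 28, 0.0419) and interferon response (0.20 with the test up, 1 of 16 by either adjustment, Irf7 at −1.46, 0.0419) all lost their calls (adjusted p = 0.742 with an estimated correlation), and each also lost it under quantile normalization (0.117).

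Each systolic line was also set against C57BL/6. FVB differed from it in 203 genes, 80 higher and 123 lower (176 and 142 under quantile normalization; 106 to 308 without single arrays of the lines compared), led by Sema6c (3.79), Rad51b (3.60), Cryl1 (3.00) and Aif1l (2.58), and by Rasl10a (−2.91), Otub1 (−2.90), Junb (−2.76) and Lcn2 (−2.64). B2KO differed in 1260 genes, 192 higher and 1068 lower, with a median of −0.41 over all genes (610 and 534 under quantile normalization, 372 and 516 with arrays centred on their genes). Single arrays of the lines compared moved these counts by over 1.5 times. For FVB they were treated FVB replicate 9 (119), untreated C57BL/6 replicates 1 (106), 2 (109), 3 (107), 4 (131), 6 (132) and 10 (308), and treated C57BL/6 replicates 3 (124) and 4 (123). For B2KO they were untreated B2KO replicate 8 (2466), treated B2KO replicate 10 (665) and untreated C57BL/6 replicates 1 (761), 2 (829) and 6 (679). Sema6c (3.77), Epcam (2.83), Cngb3 (2.61) and Tuba3b (2.24) led the higher responses there, and Hnrnpl (−4.28), Ucp1 (−3.84), Fos (−3.09) and Btg2 (−3.08) the lower. Ucp1 and Fos did not pass in that comparison under quantile normalization (adjusted p = 0.104 and 0.0515) or with array weights (0.0688 and 0.0628). Nor did they in the fit of the groups compared (0.0542 and 0.0941) or without 3 arrays (0.0878 and 0.0577). Ucp1 was also lost with centring (0.0733), with trend and robust moderation (0.0523) and without the failed array (0.0585). Immediate early genes responded less in both (2 of 15 passing in FVB and 7 when adjusted over the list alone, adjusted p = 6.96e-05; 11 of 15 in B2KO by either adjustment, 9.8e-06), calls lost at adjusted p = 0.854 and 0.693 with an estimated correlation. The 2 differences use the same C57BL/6 arrays, so they are not independent of each other.

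Between B2KO and FVB themselves, limma called 0 genes, with 1066 at an unadjusted p under 0.05 where chance gives 598, and a median difference of −0.30 over all genes. With array weights it called 10, and with a component of the residuals as a covariate 946. That component lies mainly on treated B2KO replicate 10 and leaves every change as it was. It takes up that array's spread while its share in the B2KO mean stays, so the 946 are no check on that array. Cell cycle genes responded less in B2KO (median −1.06, 0 of 21 passing, 9 when adjusted over the list alone, adjusted p = 2.58e-08), as did matrix genes (−0.64, 0 of 38 and 4 when adjusted over the list alone, 0.000387). Top2a differed by −2.31 (SE 0.615), which did not pass over all genes (adjusted p = 0.496). The 2 list calls were lost with an estimated correlation (adjusted p = 0.488 and 0.954).

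The response of B6129SF2/J was then placed against both. Against C57BL/6, 677 genes differed, 286 higher and 391 lower with a median of −0.13 (666 and 359 under quantile normalization, 618 and 505 with arrays centred on their genes). Sema6c (3.63 ± 0.78), Cryl1 (3.05), the matrix gene Aspn (2.63) and Ccdc85a (2.49 ± 0.41) responded more, and the long noncoding RNA Malat1 (−4.14 ± 0.77), Zbtb12 (−3.46 ± 0.44), Hnrnpl (−3.16) and Zeb2 (−3.15) less. Cryl1 and Zeb2 did not pass when their probe sets were averaged (0.36, adjusted p = 0.388 and −0.13, 0.77), nor Aspn without probe sets of shared sequence (0.94, 0.323). Against the systolic lines, 17 genes differed, 14 higher and 3 lower with a median of 0.12: Sprr1a (1.95 ± 0.44), Bdh1 (1.86), the metallothionein gene Mt2 (1.75) and Wdfy1 (1.54) higher, and Rad51b (−2.83 ± 0.64, adjusted p = 0.0378), Nxpe4 (−2.51) and Cacna1s (−1.29) lower. This count was unstable: without single arrays it ran from 5 to 25, with 19 of 64 arrays moving it by over 1.5 times and untreated B6129SF2/J replicates 6 and 7 giving 5 each. With probe sets averaged Rad51b (−1.30, adjusted p = 0.267), Wdfy1 (0.85, 0.244) and Bdh1 (0.0862) did not pass. In a fit of the groups compared 2 of the 7, Sprr1a and Cacna1s, passed, and without 8 arrays Sprr1a (0.0824), Mt2 (0.0991) and Wdfy1 (0.0824) did not. Immediate early genes responded less in B6129SF2/J than in C57BL/6 (5 of 15, 7 when adjusted over the list alone, median −1.10, adjusted p = 0.000128), a call lost at adjusted p = 0.952 with an estimated correlation. They did so in the systolic lines too, but both comparisons use the same C57BL/6 arrays. The rise of these genes in C57BL/6 therefore enters each of them.

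A score of the derivation genes asked whether they moved in B6129SF2/J, whose arrays took no part in choosing them. The score is the mean of 145 genes with a higher response in the systolic lines, among them Sema6c, minus the mean of 395 with a lower one, such as Junb and Hnrnpl, halved, each relative to the untreated arrays of the line. Treated B6129SF2/J arrays scored 0.037 ± 0.097 (SD, n = 12) and untreated ones 0 ± 0.191 (SD, n = 10), a difference of 0.037 log2 units (two-sided permutation test, p = 0.563). Treated C57BL/6 arrays lay at −1.20 ± 0.24 (SD, n = 10), from −1.51 to −0.88. Each was scored with genes chosen without that array but with the other treated C57BL/6 arrays, so these scores are not independent of the choice of genes. Treated FVB and B2KO arrays lay at −0.02 ± 0.32 and 0.15 ± 0.34 (SD, n = 12 and 10). Untreated ones lay at 0.07 ± 0.12 and 0.09 ± 0.49 (SD, n = 10 each), so the score hardly moved in the systolic lines themselves. A difference near 0 in B6129SF2/J therefore does not set it apart from the systolic lines. The lowest treated B6129SF2/J array scored −0.16, above every treated C57BL/6 array, and untreated C57BL/6 arrays ranged from −0.92 to 0.62. Of the 540 genes, 315 changed in B6129SF2/J with the sign of the difference between the systolic lines and C57BL/6. Among those past the threshold in B6129SF2/J, 16 had that sign and 17 the other. With the 83 genes of smallest p, the difference was 0.0045 (permutation p = 0.96).

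**Figure D4:**
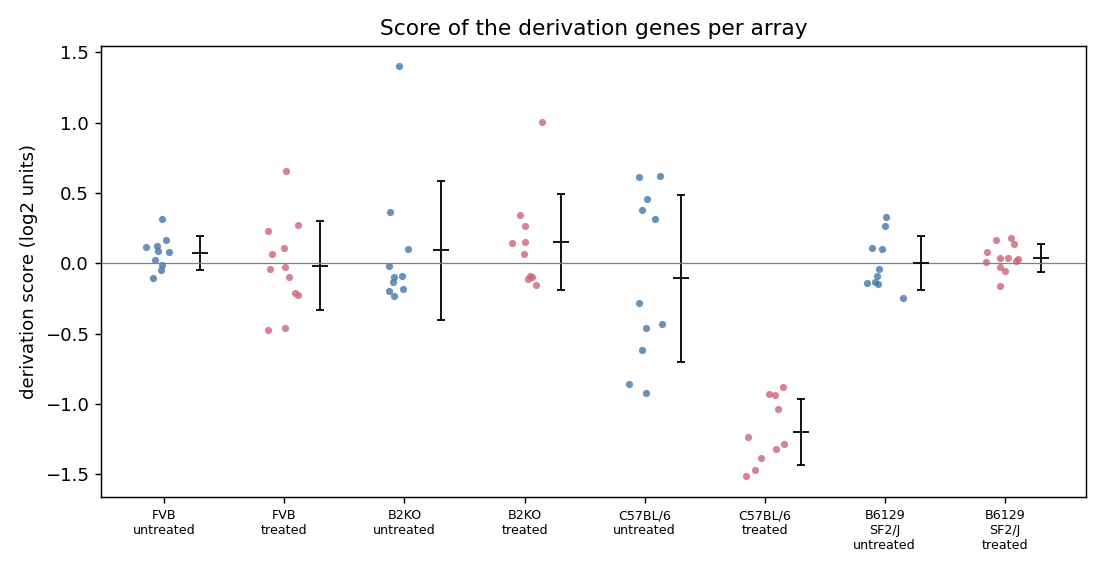
Score of the derivation genes (log2 units) per array, by line and treatment; points are arrays and bars are mean and SD. Treated C57BL/6 arrays lie between −1.51 and −0.88, and treated B6129SF2/J arrays between −0.16 and 0.18, beside untreated ones between −0.25 and 0.33.

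**Figure D5:**
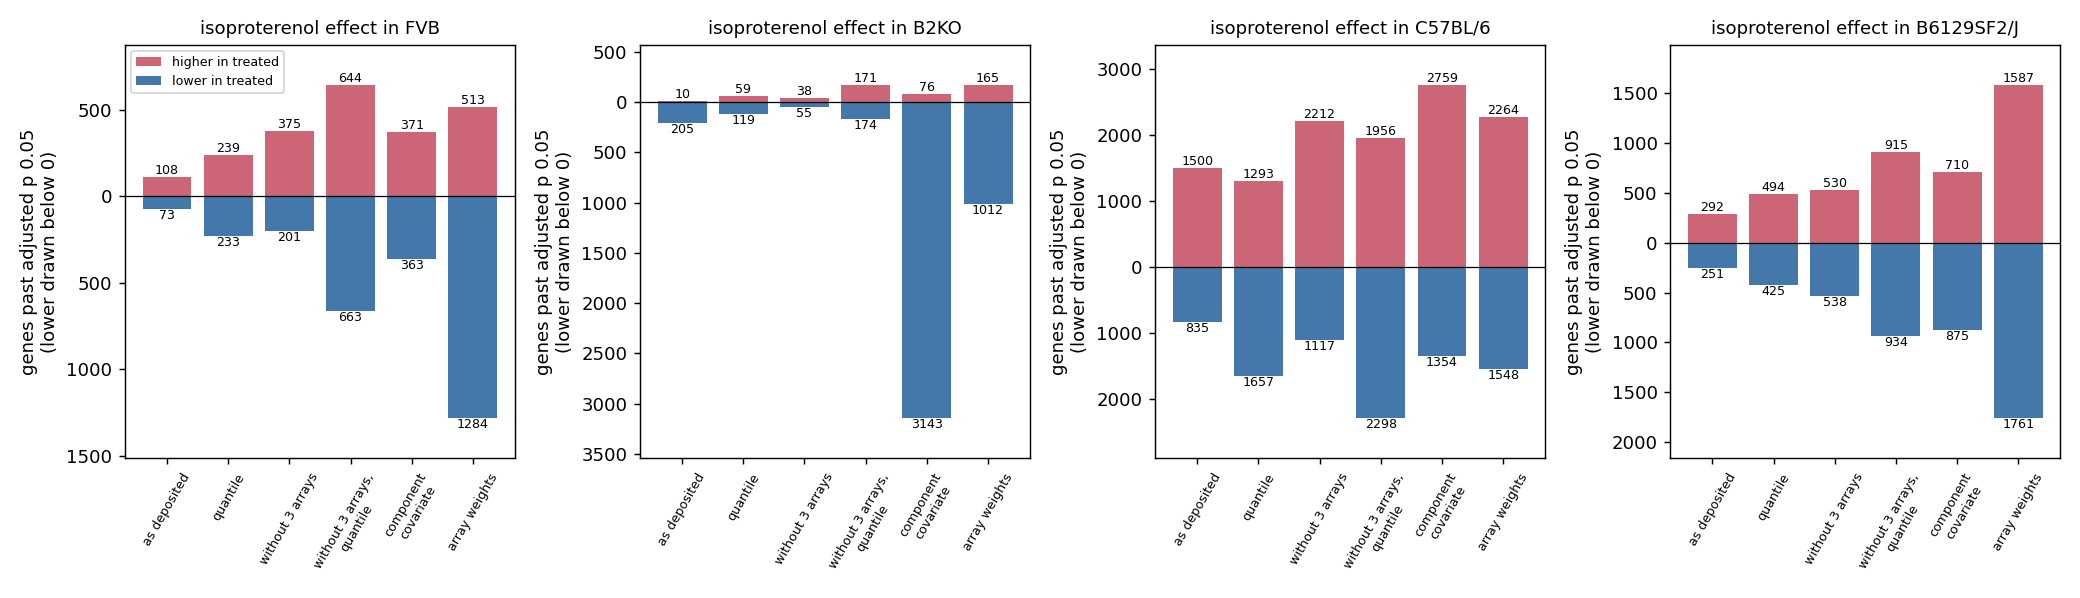
Genes past an adjusted p of 0.05 in the isoproterenol effect of each line, higher (above 0) and lower (below 0) with treatment, as deposited and under 5 alternatives. In B2KO the count ranges from 93 without 3 arrays to 3219 with a component of the residuals as a covariate, and in C57BL/6 from 2335 as deposited to 4254. The component takes up the spread of treated B2KO replicate 10 and leaves its share in the B2KO mean.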

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

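The 3 patterns weighed in this part, and the tests of them, were chosen only after the values had been seen, while the other splits of the arrays were planned before. For treated FVB replicate 2 in the first pattern, the scaling and degraded RNA in the second and the lowering in the third, the tests given replaced earlier ones whose outcomes were known. An array was picked out where it lay far from the rest of its group by Dixon's ratio, which chance alone does in about 1 in 20 groups. This was asked only of the 5 groups of 10 arrays, so 3 larger groups, treated FVB, untreated C57BL/6 and treated B6129SF2/J, were not examined. Of 115 tests, 26 did so where about 6 would by chance.

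Treated B2KO replicate 10 was the most frequent: its median r was 0.573, its 75th percentile 1.28, its Gapdh difference 1.06 and its score 1.00. In it Nppa read 3.96, Nppb 2.43, Acta1 0.91, Ankrd1 4.11, Col1a1 0.33 and Ppargc1a 0.12, where the nearest other arrays of its group read 9.90, 7.69, 6.41, 9.17, 5.55 and 3.50. Untreated B2KO replicate 8 had a median r of 0.831, a 75th percentile of 4.22, a Gapdh difference of 7.31, a score of 1.40 and Timp1 at −0.44. Untreated FVB replicate 10 had a median r of 0.902, a Gapdh difference of 2.06 and Myh7 at 10.32, and untreated B6129SF2/J replicate 8 had a Gapdh difference of 4.35. Untreated B2KO replicate 1 had Xist at 3.20, Eif2s3y at −0.57 and Ppargc1a at 7.52. Single genes stood apart in other arrays: Myh6 in untreated B2KO replicate 2 (12.53) and untreated B6129SF2/J replicate 3 (12.76), Acta1 in untreated B6129SF2/J replicate 7 (7.17) and Atp2a2 in treated C57BL/6 replicate 7 (10.4).

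Effects differed between lines in 1059 genes for the systolic lines against C57BL/6, 203 for FVB against C57BL/6, 1260 for B2KO against C57BL/6, 677 for B6129SF2/J against C57BL/6 and 17 for B6129SF2/J against the systolic lines. Differences between the systolic lines and C57BL/6 were named for Sema6c (3.78), Rad51b (2.65), Cryl1 (2.61), Epcam (2.37), Uroc1 (2.37), Aif1l (2.31), B3galt2 (2.13), Med18 (2.11), Hnrnpl (−3.43), Ucp1 (−3.29), Otub1 (−2.97), Rasl10a (−2.80), Junb (−2.78), Fos (−2.64), Gpc3 (−2.63) and Zbtb12 (−2.62). For FVB against C57BL/6 they were Sema6c (3.79), Rad51b (3.60), Cryl1 (3.00), Aif1l (2.58), Rasl10a (−2.91), Otub1 (−2.90), Junb (−2.76) and Lcn2 (−2.64), and for B2KO against C57BL/6 Sema6c (3.77), Epcam (2.83), Cngb3 (2.61), Tuba3b (2.24), Hnrnpl (−4.28), Ucp1 (−3.84), Fos (−3.09) and Btg2 (−3.08). For B6129SF2/J against C57BL/6 they were Sema6c (3.63), Cryl1 (3.05), Aspn (2.63), Ccdc85a (2.49), Malat1 (−4.14), Zbtb12 (−3.46), Hnrnpl (−3.16) and Zeb2 (−3.15). Against the systolic lines they were Sprr1a (1.95), Bdh1 (1.86), Mt2 (1.75), Wdfy1 (1.54), Rad51b (−2.83), Nxpe4 (−2.51) and Cacna1s (−1.29).

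Arrays were regrouped at random in up to 100 splits per comparison, the real one included. For 12 of the 13 comparisons that called a gene, at most 4 of 100 splits reached the real count, the real one included. For differences between effects, treatment was reassigned within every line, which removes the effects themselves too. Those splits ask about no effect in any line, so they cannot tell whether effects differ between lines by chance. The 13 comparisons were not adjusted for each other. The real and highest other counts were 181 and 40 in FVB, 2335 and 1553 in C57BL/6, 543 and 4 in B6129SF2/J, 1059 and 136 for the systolic lines against C57BL/6, 203 and 56 for FVB against C57BL/6, 1260 and 7 for B2KO against C57BL/6, 677 and 27 for B6129SF2/J against C57BL/6, and 17 and 6 for B6129SF2/J against the systolic lines, each reached by 1 of 100 splits, the real one. Between untreated lines they were 1460 and 311 for FVB against C57BL/6, 1188 and 351 for B2KO against C57BL/6 and 917 and 66 for B6129SF2/J against C57BL/6, each 1 of 100, and 2 and 17 for B2KO against FVB, reached by 4 of 100. For the lists over the 4 effects they were 33 and 35, reached by 3 of 100. In B2KO chance was not excluded: 6 of 100 splits called at least 215 genes and 1 called 2076, which points to structure among those arrays apart from treatment. For B2KO against FVB the real count was 0, which all 100 splits reach by necessity, so nothing was tested there, and 1 split called 449. In C57BL/6 a split called 1553 genes. How far it overlapped the real treatment labels was not examined, so it does not show structure among those arrays apart from treatment.

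The first pattern was that 2 treated arrays carried strain markers unlike their lines. For treated FVB replicate 2, an exchange with a C57BL/6 array of this series would leave a C57BL/6 array nearer to another background. There were 0 such arrays, which argues against an exchange. This count was known from the strain check beforehand, so it was not an independent test. A C57BL/6 mouse or array under the label of replicate 2 is a candidate explanation. At 33 probe sets that took no part in picking the array out, 69.7% lay near the C57BL/6 mean. The range was 51.5% to 72.7% in treated C57BL/6 arrays, and B6129SF2/J reached at most 51.5%. A mixture with RNA of a C57BL/6 animal in treated B2KO replicate 7 was argued against. Such a mixture would raise all markers higher in C57BL/6, and 16 of 26 lay near the FVB mean. The nearest other background of this array was B6129SF2/J, at a distance of 1.56, and a mixture with such an animal was not tested. Degraded RNA was argued against too, with a highest Gapdh difference of 0.110 in these 2 arrays. A mouse of mixed background could give markers of both kinds in replicate 7, which was not tested.

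The second pattern was that the genes leading the C57BL/6 effect also differed between untreated C57BL/6 arrays, in 6 of 16 genes with a larger SD than in untreated FVB and B6129SF2/J. That count is close to what 3 lines of equal spread would give, so it shows no clear excess in C57BL/6 gene by gene. The derivation score did spread more there: its SD among untreated arrays was 0.594, against 0.119 in FVB, 0.191 in B6129SF2/J and 0.492 in B2KO. In untreated C57BL/6, 5 of 11 arrays scored above 0, and none lay between −0.28 and 0.31. The score's genes were chosen with C57BL/6 arrays, so this spread is not independent of that choice. Genes called in C57BL/6 varied together in arrays of the other 3 lines, with a mean signed correlation of 0.106. The highest of 100 random sets gave 0.0144. Treated arrays were among them, each taken relative to its group, so an uneven response to isoproterenol could give this value too. Variation between arrays along the same genes is a candidate explanation for part of the effect, but was not shown to be apart from isoproterenol. Scaling by the submitters was argued against as the source of the spread of these genes, and of that alone. The SD of the 16 leading genes among untreated C57BL/6 arrays kept a median of 1.03 of its size under quantile normalization (lowest 0.804). Counts of genes were not part of that test, and their split between higher and lower did turn under quantile normalization. Degraded RNA in untreated replicate 11 was argued against, as the SD kept a median of 1.01 of its size without that array (lowest 0.898). A response that adds to such variation could give the same values, and the 2 were not separated.

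The third pattern was that nearly all genes past the threshold in B2KO were lower in treated arrays. One failed array and the scaling to each array's median were a candidate explanation for part of it, since the median shift of all genes moved from −0.285 to −0.0813 without that array. A lowering of most responding genes by isoproterenol stayed open: without that array 30.2% of 43 genes were higher, against 4.65% of 215 with it.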

How the results depend on the processing

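The alternatives that leave out the failed array, 3 arrays or 8 arrays, and quantile normalization of the lists, were added after the values had been seen, and no other alternative was added. Of the values of named genes under alternatives chosen before the data were examined, 8868 kept their direction and side of the threshold. A further 575 came past it and 206 lost it. Direction changed in 66 that passed neither before nor after, and in 3 that passed before or after. Under the added alternatives these numbers were, in the same order, 2499, 387, 59, 85 and 1. With each array of the groups compared left out in turn they were 21289, 204, 702, 56 and 0. As to signal over background, the stricter filter left 8728 of 11962 genes and changed the FVB count to 129 from 181, less than settings that act on the spread between arrays did (1797 with array weights and 847 without 8 arrays). Which limit weighs most was not tested. Counts as given were 181 in FVB, 2335 in C57BL/6, 215 in B2KO, 543 in B6129SF2/J, 1059 in systolic minus C57BL/6, 203 in FVB minus C57BL/6, 1260 in B2KO minus C57BL/6, 0 in B2KO minus FVB, 677 in B6129SF2/J minus C57BL/6, 17 in B6129SF2/J minus systolic, 1460 in untreated FVB minus C57BL/6, 2 in untreated B2KO minus FVB, 1188 in untreated B2KO minus C57BL/6 and 917 in untreated B6129SF2/J minus C57BL/6. Counts of the next 2 paragraphs differ from these by more than 1.5 times, and the cause was not tested, apart from the fewer genes or arrays that a setting itself brings. The failed array belongs to B2KO, so leaving it out kept the changes in other lines, as for Col1a1 in FVB (1.40) and Ppargc1a in B6129SF2/J (−0.996). Their counts moved then only through the spread that all groups share in the fit. The residual component likewise kept all changes.

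With quantile normalization, counts moved to 472 in FVB, 919 in B6129SF2/J, 318 in FVB minus C57BL/6, 1025 in B6129SF2/J minus C57BL/6 and 30 in B6129SF2/J minus systolic. With arrays centred on their genes, counts moved to 501 in FVB, 467 in B2KO, 1012 in B6129SF2/J, 398 in FVB minus C57BL/6, 1123 in B6129SF2/J minus C57BL/6, 1818 in untreated B2KO minus C57BL/6 and 1425 in untreated B6129SF2/J minus C57BL/6. With array weights, counts moved to 1797 in FVB, 3812 in C57BL/6, 1177 in B2KO, 3348 in B6129SF2/J, 2459 in systolic minus C57BL/6, 1308 in FVB minus C57BL/6, 2238 in B2KO minus C57BL/6, 10 in B2KO minus FVB, 3078 in B6129SF2/J minus C57BL/6, 746 in B6129SF2/J minus systolic, 2809 in untreated FVB minus C57BL/6, 117 in untreated B2KO minus FVB, 3626 in untreated B2KO minus C57BL/6 and 3323 in untreated B6129SF2/J minus C57BL/6. With a residual component as covariate, counts moved to 734 in FVB, 4113 in C57BL/6, 3219 in B2KO, 1585 in B6129SF2/J, 3336 in systolic minus C57BL/6, 1075 in FVB minus C57BL/6, 4203 in B2KO minus C57BL/6, 946 in B2KO minus FVB, 2023 in B6129SF2/J minus C57BL/6, 143 in B6129SF2/J minus systolic, 2895 in untreated FVB minus C57BL/6, 14 in untreated B2KO minus FVB, 2370 in untreated B2KO minus C57BL/6 and 2633 in untreated B6129SF2/J minus C57BL/6. With the stricter filter, counts moved to 1382 in C57BL/6, 332 in B2KO, 342 in B6129SF2/J, 573 in systolic minus C57BL/6, 54 in FVB minus C57BL/6, 294 in B6129SF2/J minus C57BL/6, 9 in B6129SF2/J minus systolic, 948 in untreated FVB minus C57BL/6, 1 in untreated B2KO minus FVB, 694 in untreated B2KO minus C57BL/6 and 536 in untreated B6129SF2/J minus C57BL/6. Without a filter, counts moved to 130 in B2KO, 127 in FVB minus C57BL/6 and 10 in B6129SF2/J minus systolic. In fits of the groups compared, counts moved to 0 in B2KO, 2783 in B6129SF2/J, 562 in systolic minus C57BL/6, 246 in B2KO minus C57BL/6, 2107 in B6129SF2/J minus C57BL/6, 8 in B6129SF2/J minus systolic, 1 in untreated B2KO minus FVB and 1561 in untreated B6129SF2/J minus C57BL/6. With trend and robust moderation, counts moved to 1 in untreated B2KO minus FVB.

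Without the failed array, counts moved to 377 in FVB, 43 in B2KO, 1007 in B6129SF2/J, 446 in FVB minus C57BL/6, 665 in B2KO minus C57BL/6, 1285 in B6129SF2/J minus C57BL/6, 6 in untreated B2KO minus FVB and 1636 in untreated B6129SF2/J minus C57BL/6. Without 3 arrays, counts moved to 576 in FVB, 93 in B2KO, 1068 in B6129SF2/J, 317 in FVB minus C57BL/6, 568 in B2KO minus C57BL/6, 1330 in B6129SF2/J minus C57BL/6, 2193 in untreated FVB minus C57BL/6, 7 in untreated B2KO minus FVB and 1703 in untreated B6129SF2/J minus C57BL/6. Without 3 arrays and with quantile normalization, counts moved to 1307 in FVB, 4254 in C57BL/6, 345 in B2KO, 1849 in B6129SF2/J, 1613 in systolic minus C57BL/6, 808 in FVB minus C57BL/6, 2066 in B6129SF2/J minus C57BL/6, 74 in B6129SF2/J minus systolic, 3375 in untreated FVB minus C57BL/6, 18 in untreated B2KO minus FVB, 2622 in untreated B2KO minus C57BL/6 and 2451 in untreated B6129SF2/J minus C57BL/6. Without 8 arrays, counts moved to 847 in FVB, 3998 in C57BL/6, 129 in B2KO, 1201 in B6129SF2/J, 2071 in systolic minus C57BL/6, 690 in FVB minus C57BL/6, 1968 in B2KO minus C57BL/6, 1978 in B6129SF2/J minus C57BL/6, 8 in B6129SF2/J minus systolic, 2210 in untreated FVB minus C57BL/6, 2867 in untreated B2KO minus C57BL/6 and 2309 in untreated B6129SF2/J minus C57BL/6.

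With each array of the groups compared left out in turn, counts ran from 135 to 283 in FVB, 1864 to 2520 in C57BL/6, 43 to 844 in B2KO, 450 to 544 in B6129SF2/J, 658 to 1848 in systolic minus C57BL/6, 106 to 308 in FVB minus C57BL/6, 665 to 2466 in B2KO minus C57BL/6, 0 to 0 in B2KO minus FVB, 462 to 839 in B6129SF2/J minus C57BL/6, 5 to 25 in B6129SF2/J minus systolic, 1145 to 1654 in untreated FVB minus C57BL/6, 1 to 3 in untreated B2KO minus FVB, 935 to 1732 in untreated B2KO minus C57BL/6 and 628 to 1072 in untreated B6129SF2/J minus C57BL/6. Arrays of other groups were not left out for these ranges, although all groups share 1 fit. Without the failed array, treated B2KO replicate 10, several counts of other lines lay outside these ranges, as given above. For FVB the count moved to 283 without FVB treated 2. For B2KO the count moved to 127 without B2KO untreated 2, 367 without B2KO untreated 5, 111 without B2KO untreated 6, 104 without B2KO untreated 9, 103 without B2KO treated 2, 682 without B2KO treated 3, 844 without B2KO treated 5, 747 without B2KO treated 6 and 43 without B2KO treated 10. For systolic minus C57BL/6 the count moved to 666 without C57BL/6 untreated 1, 700 without C57BL/6 untreated 2, 658 without C57BL/6 untreated 6 and 1848 without B2KO untreated 8. For FVB minus C57BL/6 the count moved to 119 without FVB treated 9, 106 without C57BL/6 untreated 1, 109 without C57BL/6 untreated 2, 107 without C57BL/6 untreated 3, 131 without C57BL/6 untreated 4, 132 without C57BL/6 untreated 6, 308 without C57BL/6 untreated 10, 124 without C57BL/6 treated 3 and 123 without C57BL/6 treated 4. For B2KO minus C57BL/6 the count moved to 761 without C57BL/6 untreated 1, 829 without C57BL/6 untreated 2, 679 without C57BL/6 untreated 6, 2466 without B2KO untreated 8 and 665 without B2KO treated 10. For B6129SF2/J minus systolic the count moved to 9 without FVB untreated 3 or B6129SF2/J treated 6 or B6129SF2/J treated 8 or B2KO treated 2, 10 without FVB untreated 4 or FVB treated 3 or B2KO untreated 3 or B2KO treated 7, 8 without FVB untreated 7 or FVB untreated 9 or B6129SF2/J untreated 2 or B6129SF2/J untreated 4 or B6129SF2/J treated 5, 11 without FVB treated 5, 5 without B6129SF2/J untreated 6 or B6129SF2/J untreated 7 and 7 without B6129SF2/J untreated 10 or B6129SF2/J treated 1 or B6129SF2/J treated 7. For untreated B2KO minus FVB the count moved to 1 without FVB untreated 10 or B2KO untreated 2 or B2KO untreated 4 or B2KO untreated 8 or B2KO untreated 10. The cause was not tested.

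The replicate block by the number in the labels changed no count by more than 1.5 times (181 in FVB, 2343 in C57BL/6, 215 in B2KO, 544 in B6129SF2/J and 1076 in systolic minus C57BL/6). Its consensus correlation was 0.00142. Pairs of the same number had a median r of 0.0088 in FVB, −0.031 in C57BL/6, 0.041 in B2KO and 0.0044 in B6129SF2/J, with 2 of 10, 0 of 10, 3 of 9 and 1 of 10 pairs over 0.1, and an array correlated best with its own number in 0, 0, 1 and 1 pairs. Nothing in the values shows a pairing.

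Among values that passed before or after, direction reversed for Atp2a2 in C57BL/6 with probe sets averaged (−0.0725, adjusted p = 0.841). It also reversed for Idh3b in C57BL/6 without probe sets of shared sequence (0.58, 0.0324). The others were Rgs5 in B2KO without 3 arrays and with quantile normalization (0.39, 0.0413) and Hspa8 in systolic minus C57BL/6 with probe sets averaged (−0.0199, 0.966). The glucose transport and glycolysis list in B2KO turned upward without 3 arrays and with quantile normalization (adjusted p = 0.0149). Other probe sets entered in 3 of these cases, and the cause was not tested in the others. Of all list tests, 78 passed with the preset correlation, 2 with an estimated one, 67 with quantile normalization, 101 without the failed array, 102 without 3 arrays and 77 without 3 arrays and with quantile normalization. The score difference in B6129SF2/J ran from 0.0045 to 0.0991 over the alternatives (lowest permutation p 0.122), and from 0.0092 to 0.0733 with each B6129SF2/J array left out in turn.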

Other observations

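No hypothesis beyond the patterns weighed was tested, and 1 gene here, BC023105, was chosen after its values were seen. Untreated lines differed at genes with changes of a size that a polymorphism under the probes can also give. Untreated FVB against C57BL/6 hearts had Gdpd3 higher by 9.13 ± 0.74 and Cap1 (5.61), Tmem87a (5.12), Fmn1 (4.92) and Serpina1b (4.47) higher, and Mndal (−5.66), Pttg1 (−5.41), Ndufs5 (−4.85), the cardiac kinase gene Tnni3k (−4.52 ± 0.26, adjusted p = 3.93e-26) and Nxpe4 (−4.37) lower, all in 10 of 10 FVB arrays. In all 1460 genes passed, 526 higher and 934 lower (1262 higher and 911 lower with arrays centred on their genes). B2KO against C57BL/6 gave 1188, 556 higher and 632 lower (1147 and 671 with arrays centred), led by Gdpd3 (8.97), Cap1 (5.56), Fmn1 (5.33), Tmem87a (4.95) and Serpina1b (4.09), with Mndal (−6.29), Pttg1 (−5.13), Ndufs5 (−4.78), Nxpe4 (−4.71) and Trim34a (−4.27) lower. Between untreated B2KO and FVB limma called 2 genes, with 466 at an unadjusted p under 0.05: Plet1os (−3.67 ± 0.73, adjusted p = 0.0178, 10 of 10 B2KO arrays below) and BC023105 (2.42, 0.00467). Plet1os did not pass in a fit of the groups compared (0.157), with trend and robust moderation (0.0657) or without 8 arrays (0.089). The count was 1 without untreated FVB replicate 10 or untreated B2KO replicate 2, 4, 8 or 10.

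Untreated B6129SF2/J against C57BL/6 gave 917 genes, 429 higher and 488 lower, with a median of 0.11 (818 and 607 with arrays centred). Gdpd3 (7.07), Pam (4.53), Cap1 (3.86, 8 of 10 arrays), Adat2 (3.16) and Ptprn2 (3.15) were higher, and Rgcc (−3.46), Sema6c (−3.37), Cryl1 (−2.86), Med18 (−2.47) and Rpgrip1 (−2.45) lower, the last not passing when its probe sets were averaged (−0.48, adjusted p = 0.191). Sema6c, Cryl1 and Med18 were also among the largest falls with isoproterenol in C57BL/6. Both comparisons use the same untreated C57BL/6 arrays, so high values in those arrays would make a gene low in both. Fatty acid oxidation genes were higher (6 of 25, 7 when adjusted over the list alone, median 0.68, adjusted p = 8.57e-07; adjusted p = 0.584 with an estimated correlation), and interferon response genes lower (5 of 16, 10 when adjusted over the list alone, −0.69, 1.63e-07; adjusted p = 0.448 with an estimated correlation). Macrophage genes were lower (5 of 20, −0.26, 0.000145; adjusted p = 0.584 with an estimated correlation). Sarcomere (6 of 16, 0.73, 9.5e-07), oxidative phosphorylation (5 of 28, 0.63, 1.76e-06), calcium handling (4 of 14 higher and 1 lower, 0.39, 0.0114), the tricarboxylic acid cycle (1 of 14, 0.49, 0.0331) and cytokines (1 of 19 lower, −0.33, 0.0268) lost their calls with an estimated correlation (adjusted p = 0.584, 0.627, 0.627, 0.944 and 0.627) and under quantile normalization (0.0588, 0.272, 0.32, 0.969 and 0.117).

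Other baseline lists were higher hypertrophy-associated genes in FVB (4 of 14, median 0.51, adjusted p = 0.000568) and B2KO (4 of 14, 0.45, 0.00352) and immediate early genes in FVB (3 of 15, 0.47, 0.0164) and B2KO (4 of 15, 0.50, 0.00933), each against C57BL/6. Heat shock genes were higher in FVB (2 of 13, 0.32, 0.0453; 0.105 under quantile normalization). Interferon response genes were lower in FVB (4 of 16, −0.53, 0.00703) and B2KO (5 of 16, −0.62, 2.89e-05) and macrophage genes in B2KO (4 of 20, −0.18, 0.0144). Cytokines were lower in B2KO against FVB (0 of 19, −0.24, 0.0363; 0.0686 under quantile normalization). All lost their calls with an estimated correlation (adjusted p = 0.899 for FVB, 0.972 for B2KO against C57BL/6 except 0.819 for interferon response, and 0.996 for B2KO against FVB).

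The remaining lists that differed in response were these. Against C57BL/6, FVB responded less in fatty acid oxidation (median −0.47, adjusted p = 0.0224; adjusted p = 0.854 with an estimated correlation). B2KO responded less than C57BL/6 in sarcomere (5 of 16, −1.04, 0.0203), matrix (3 of 38, −0.89, 0.0163), fatty acid oxidation (3 of 25, −0.99, 0.0111), oxidative phosphorylation (1 of 28, −0.91, 0.0163) and adipocytes (3 of 8, −1.92, 0.0457), and the test pointed up for interferon response (0.04, 0.0457) and skeletal muscle (0.55, 0.0358). These calls were lost at adjusted p = 0.693 with an estimated correlation, and 0.244 for skeletal muscle. Under quantile normalization sarcomere (0.0591), oxidative phosphorylation (0.0504), interferon response (0.142) and skeletal muscle (0.372) did not pass, and matrix did not without 3 arrays (0.0707). B6129SF2/J responded less than C57BL/6 in fatty acid oxidation (−0.71, 0.000568), sarcomere (−0.74, 0.00844) and oxidative phosphorylation (−0.58, 0.00547) and more in cytokines (0.42, 0.00547), all lost at adjusted p = 0.952 with an estimated correlation. Sarcomere and oxidative phosphorylation did not pass under quantile normalization either (0.202 and 0.275). Against the systolic lines it responded more in matrix (0.43, 0.000245), beta-adrenergic signalling (0.24, 0.0333) and cytokines (0.24, 0.0335), and less in cell cycle (−0.25, 0.000786), lymphocytes (−0.33, 0.000245) and erythroid genes (−0.54, 0.0344), lost at adjusted p = 0.88 with an estimated correlation, and 0.221 for lymphocytes. Without 3 arrays and with quantile normalization matrix (0.098), beta-adrenergic signalling (0.0935), cytokines (0.0801), cell cycle (0.0549) and lymphocytes (0.0935) did not pass, nor did beta-adrenergic signalling without 3 arrays (0.0642).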
